A study of Mus musculus with 12 samples.

How the data were processed

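RNA-seq was made from 12 libraries of mouse renal cortex, 4 in each of 3 groups: normal control (NC), diabetic nephropathy (DN), and diabetic nephropathy with sodium butyrate (DN+NaB). All libraries carry the labels strain C57BL/6 and age 12 weeks. The labels name frozen tissue, Trizol extraction and Illumina library preparation. They do not say how diabetes was induced, nor the dose, route or duration of sodium butyrate. They give no batch, date, cage or hour of collection. The design text gives 4 mice per group, but no label ties a library to an animal, so the p-values measure the spread between these samples. The tissue label reads renal cortex, while the extraction protocol of the same samples names prefrontal cortex. Kidney and brain genes were therefore looked at in every library.

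The deposited values are whole-number counts per gene symbol, not normalized, in 1 table that covers all libraries. HISAT2 2.0.4 is named in the submitters' processing notes. The counting program, its treatment of strand and of reads with several matches, the annotation and the genome build are not given in the sources used here. Genes that share reads with near-identical copies, overlapping genes and antisense genes are therefore uncertain, since the counting could have assigned their reads to either member. No coordinates are given. A RefSeq gene table of the GRCm38.p6 assembly was used only for names, gene types and the order of genes along chromosomes; 16391 of the 17530 tested symbols matched it. Every column name of the deposited table matched 1 sample title, and groups were taken from the titles and the disease and treatment labels.

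The table held 46095 gene symbols, of which 18156 had no count in any library. Total counts ran from 58394975 to 70674015 per library (median 63588713). The median standard error of a log2 fold change was 0.17 in each comparison, over genes above 1 CPM. No 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom between a pair was 25.5.

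Genes were filtered with filterByExpr by group, which left 17530, holding at least 99.95% of the counts of each library. Libraries were scaled with TMM factors. All 12 libraries entered 1 fit of edgeR's quasi-likelihood model with group as the only term and robust estimation (edgeR 4.0.16, R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no fold limit; all gene tests are two-sided. Log2 fold changes are given with the standard error of that fit. CPM values (counts scaled to the size of each library) use the TMM factors and are given as mean ± SD over n = 4 libraries. Log2 CPM values for gene lists and principal components used a prior count of 2, and components used the 500 most variable genes. Groups were called separated for a gene when all 4 values of 1 group lay beyond all 4 of the other, which chance gives for 2.86% of genes.

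There were 50 gene lists for kidney cell types, sex bias, disease, metabolism, stress and butyrate biology. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted within a comparison. With 1 tested member, the adrenal gland list could not be tested, which left 49. Beside this stand camera with a correlation estimated per list, and fry, whose directional p tests whether the genes of a list move one way on balance. Counts of members adjusted over the list alone are given as well. The mitochondrially encoded genes carry symbols such as ND1 in the table, and the match to the listed symbols was written after the table was seen.

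The samples' groups, the model, the filter, the gene lists, the alternatives below and the rule for naming genes were set before the data were examined. By that rule the text names up to 10 genes per direction and comparison with the smallest adjusted p among called genes with separated groups, leaving out predicted and clone-based symbols. It also names up to 4 members per described list with the smallest p, genes called in both steps of the disease and treatment series, and 13 genes whatever their values: Havcr1, Lcn2, Nphs1, Slc5a2, Slc5a1, Col1a1, Col4a1, Fn1, Tgfb1, Ccl2, Pck1, Hdac2 and Slc16a1. Some other genes that the rule names, and 1 of the 21 values that stood apart from their group, are not reported here. Genes named outside the rule, or beside values other than those it names them for, were chosen after the data were seen: the genes that checked tissue and sex (Lrp2, Umod, Snap25, Slc17a7, Mbp, Gfap, Xist and Ddx3y), Gpx3 as a share of counts, Hbb-bs, the clock genes given by their phase, Rpl3, its 2 copies and Kl. So were the adipocyte genes Adipoq and Fabp4 where their counts in NC and DN are given.

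The comparisons of DN with NC and of DN+NaB with DN share the DN libraries, so their fold changes are negatively related by chance. Observed counts and covariances were therefore set beside 20 simulations of unchanged groups, beside the overlap of independent lists, and beside values with the DN libraries divided into 2 for each comparison over 6 assignments. The comparisons of DN and DN+NaB with NC were treated likewise by dividing the NC libraries.

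Alternatives were RLE and upper quartile factors, library size only, no low-count filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, non-robust estimation, only the 2 groups compared, the replicate number as a block, a log2 limit of 1, and leaving out each library in turn. A fit on protein-coding genes only was added after the data were seen. All 35 splits of the 8 libraries of a comparison into 4 and 4 were fitted in the same way.

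The gene tests were checked on simulated data drawn from the real means and library sizes, with 17262 genes in the fit. For DN against NC, 65 of 100 genes changed 2-fold and 93 of 100 changed 4-fold were called. There were 9 calls among the 17330 genes simulated as unchanged, some of which the filter had removed before the fit. For DN+NaB against DN the numbers were 68 of 100, 92 of 100 and 8.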

Results

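Counts per gene were compared between renal cortex libraries of normal control mice (NC), mice with diabetic nephropathy (DN, kidney disease of diabetes) and mice with diabetic nephropathy given sodium butyrate (DN+NaB). Butyrate is a short-chain fatty acid made by gut bacteria, and it inhibits histone deacetylases. There were 4 libraries per group, with 58394975 to 70674015 counts each (median 63588713), and 17530 genes were tested. Kidney genes were abundant in every library: Lrp2, the endocytic receptor megalin, had 547305 to 852758 counts, and Umod, the uromodulin gene of the thick ascending limb, had 165229 to 481314. The neuronal gene Snap25 had 0 counts in all 12 libraries, which allows up to 3 counts in each, and Slc17a7 had 0 to 2. Mbp, a myelin gene, had 942 to 1501 and the glial Gfap 2 to 41. The 10 adrenal gland genes summed to 0.307 to 0.599 CPM in NC, 0.509 to 1.03 in DN and 0.353 to 0.655 in DN+NaB. Xist, transcribed from the inactive X chromosome, had 0 to 5 counts, while the Y-linked Ddx3y had 164 to 832. The single genes named here were chosen after their values were seen, as was Gpx3.

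The groups differed in the makeup of their counts. Gpx3, the secreted glutathione peroxidase made by the proximal tubule, took 4.25% ± 0.51 of counts in NC, 6.63% ± 0.39 in DN and 6.74% ± 0.43 in DN+NaB (mean ± SD, n = 4 each). Mitochondrially encoded protein genes took 0.873% ± 0.256 in NC, 2.16% ± 1.20 in DN and 1.83% ± 1.18 in DN+NaB. DN replicate 3 held 0.361% and DN+NaB replicate 1 0.518%, so the 2 diseased groups spread widely in this share. On the first principal component, with 55.6% of variance, NC libraries scored -43.4 to -41.9, DN libraries 17.3 to 20.4 and DN+NaB libraries 19.3 to 27.5. On the second, with 13.8%, DN replicate 4 scored -39.7 and the other libraries -10.4 to 23.4.

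**Figure D1:**
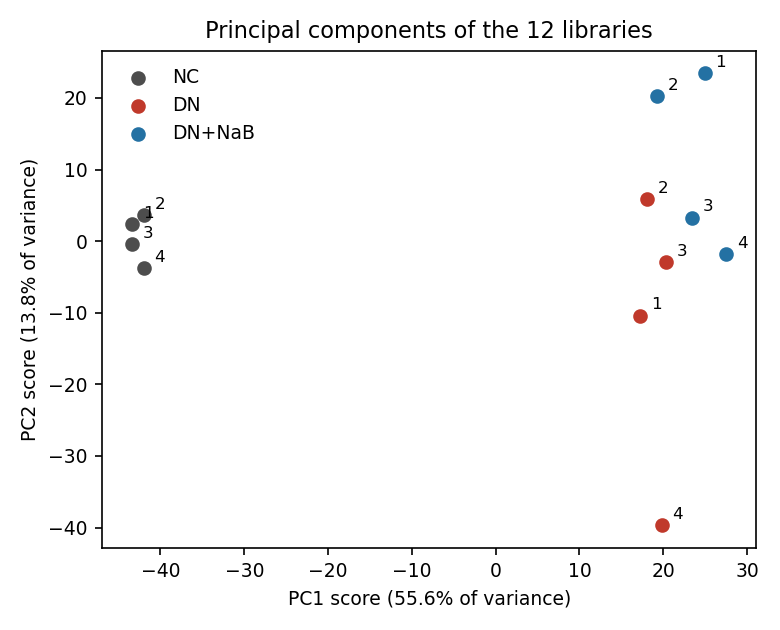
Scores of the 12 libraries on the first and second principal components of log2 CPM over the 500 most variable genes; each point is 1 library, numbered by replicate. The NC libraries lie at -43.4 to -41.9 on the first component and the diseased libraries at 17.3 to 27.5, and DN replicate 4 lies at -39.7 on the second.

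The first comparison asked which genes differed between diabetic nephropathy and normal renal cortex. Among genes of the straight part of the proximal tubule, Slc22a7, an organic anion transporter, went from 122 ± 26.3 CPM in NC to 1.35 ± 0.380 in DN (log2 fold change -6.49 ± 0.45 SE, adjusted p = 4.62e-06, n = 4 per group), and Slc7a13, an amino acid transporter, fell by 2.20 ± 0.28. C3, the central complement protein, rose by 3.75 ± 0.43 (adjusted p = 2.3e-04). The basement membrane collagen gene Col15a1 fell by 2.13 ± 0.16 and the matrix protein gene Sparc by 1.35 ± 0.14. Kap, the androgen-regulated kidney protein, fell by 2.68 ± 0.38, from 6354.5 ± 1646 to 995 ± 523 CPM.

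Several of the genes with the smallest p belong to families whose members share sequence, so their values are uncertain. Atp6v0c, a proton pump subunit, fell by 2.92 ± 0.12 (56.5 ± 6.40 to 7.45 ± 0.779 CPM) while its copy Atp6v0c-ps2 rose by 5.37 ± 0.28. The sum of both was 57.7 CPM in NC and 57.3 in DN. Rpsa, a ribosomal protein gene, fell from 585 ± 80.2 to 96.6 ± 16.2 CPM and its copy Rpsa-ps2 from 3.62 ± 0.949 to 0.195 ± 0.0522, while the copy Rpsa-ps10 rose by 2.92 ± 0.18; Rpsa and Rpsa-ps10 summed to 640 CPM in NC and 514 in DN. Ube2d-ps rose by 1.35 ± 0.12. Of 162 tested genes and copies named as pairs, the copy was called in 21 and both members in 9, in 8 of these with opposite directions. The 9 rest on 5 parent genes, with Rpsa counted 4 times and Rpl3 2 times.

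Other genes named by rule included Mrps23, of the mitochondrial ribosome, with 0.792 ± 0.174 CPM in NC and 37.1 ± 2.95 in DN (46.9-fold, adjusted p = 1.92e-10). Greb1, an oestrogen-responsive gene, rose by 5.45 ± 0.40, Pianp by 5.18 ± 0.38, Ctdnep1, a nuclear envelope phosphatase, by 4.23 ± 0.33, Cuedc1 by 4.21 ± 0.24, and Bhmt, the betaine-homocysteine methyltransferase, by 3.58 ± 0.31. Adhfe1, a mitochondrial alcohol dehydrogenase, fell by 2.12 ± 0.14 on the log2 scale, Rnps1, a splicing factor, by 2.08 ± 0.11, Atp11a, a phospholipid flippase, by 1.92 ± 0.15, and Mpv17l by 1.80 ± 0.15. Sec14l3 fell by 6.47 ± 0.52, with 401 to 851 counts per NC library and 1 to 10 per DN library.

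**Figure D2:**
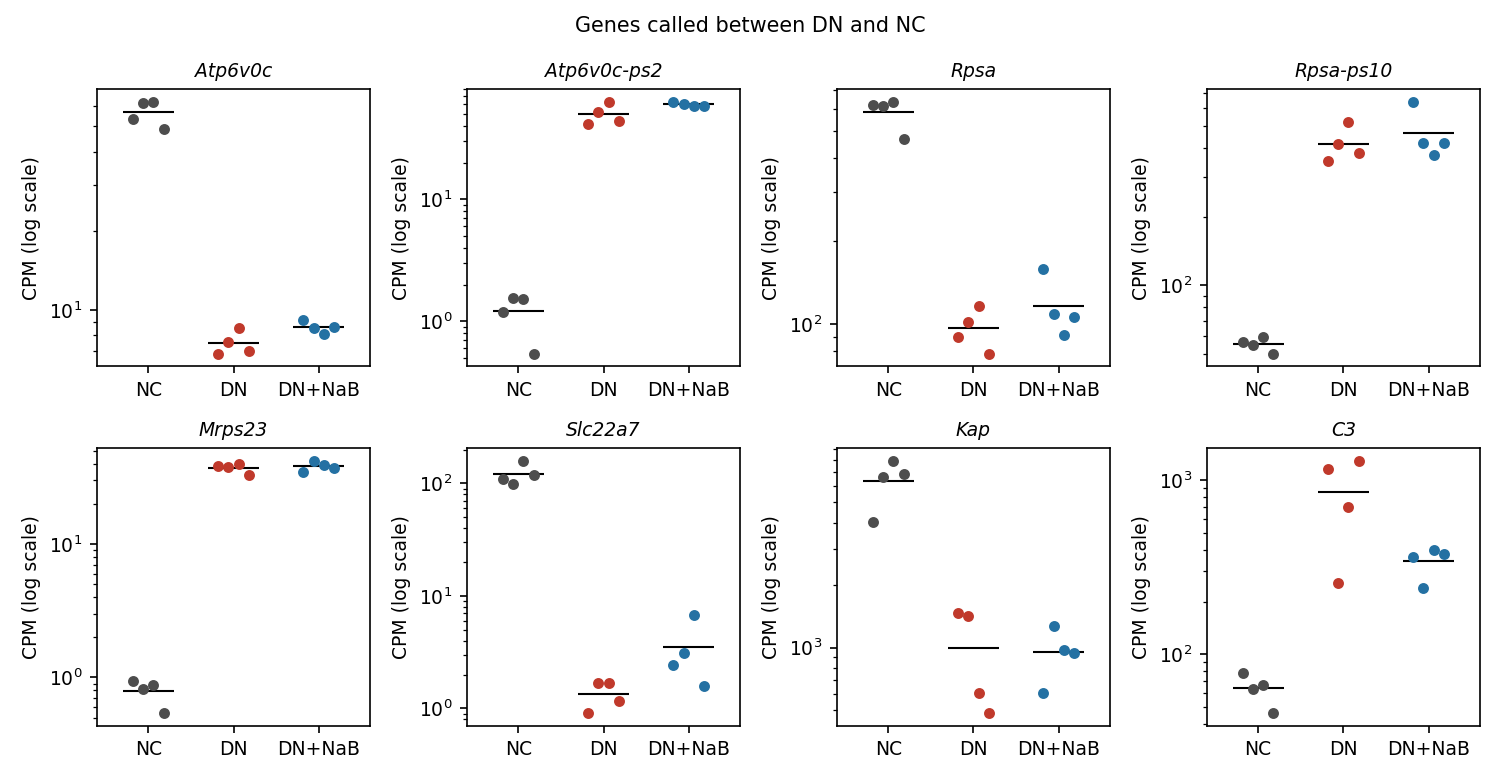
CPM of 8 genes in the 12 libraries on log axes; each point is 1 library and the bar is the group mean. Atp6v0c and Rpsa are lower, and Atp6v0c-ps2, Rpsa-ps10 and Mrps23 higher, in each of the 8 diseased libraries than in each NC library, and Slc22a7, Kap and C3 separate the same groups.

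Lists of 4 tubular segments or cell types were called. Of 10 markers of the S3 segment, the straight end of the proximal tubule, 5 fell, 1 rose and 4 were not called (median log2 fold change -0.78, camera adjusted p = 9.83e-04); 6 were lower and 1 higher adjusted over the list alone. Slc22a30 fell by 1.74 ± 0.31, while the sugar transporter gene Slc5a10 rose by 1.41 ± 0.25. Of 18 markers of the convoluted S1 and S2 segments, 4 rose and 14 were not called, with 4 higher adjusted over the list alone (median 0.27, adjusted p = 0.00978); the members that rose included Slc7a7, an amino acid transporter (0.79 ± 0.15), and Slc2a2, the basolateral glucose transporter (0.75 ± 0.16). Of 12 intercalated cell markers, 5 fell and 7 were not called, with 6 lower adjusted over the list alone (median -0.40, adjusted p = 4.16e-04); Insrr fell by 0.72 ± 0.15 and Slc26a4, the anion exchanger pendrin, by 0.72 ± 0.16. Of 13 thick ascending limb markers, 2 fell and 11 were not called, with 7 lower adjusted over the list alone (median -0.47, adjusted p = 0.0221), and Egf fell by 0.81 ± 0.18. For each of these 4 lists, adjusted p = 0.503 with an estimated correlation. The S1 and S2 call ended without DN replicate 2 or 3 (adjusted p = 0.0622 and 0.0740), and the thick ascending limb call without NC replicate 3, DN replicate 1 or DN replicate 3 (0.142, 0.0572 and 0.0609).

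Lists of genes that differ between male and female kidneys were also called. Of 11 male-biased genes, 5 fell, 1 rose and 5 were not called, with 7 lower and 2 higher adjusted over the list alone (median -1.23, adjusted p = 0.00542). Besides Kap, Acsm3, a medium-chain acyl-CoA synthetase, fell by 4.74 ± 0.41 and Odc1, the first enzyme of polyamine synthesis, by 1.30 ± 0.19, whereas Cyp4a12a, an androgen-induced hydroxylase, rose by 3.14 ± 0.37. Of 7 female-biased genes, 3 rose and 4 were not called, with 3 higher adjusted over the list alone (median 0.43, adjusted p = 0.00522); Abcc3 rose by 1.79 ± 0.22 and Cyp4a14, which is also a PPAR-alpha target, by 2.24 ± 0.27. For both lists, adjusted p = 0.503 with an estimated correlation. Without DN replicate 4 the male-biased list was not called (adjusted p = 0.0572), and without DN replicate 2 the female-biased median was 0.26. Members of the Cyp4a family are close copies of each other, so their values are uncertain.

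Lists of matrix, cell cycle and lymphocyte genes were called lower in DN, with most members not called. Of 26 extracellular matrix and fibrosis genes, 10 fell, 0 rose and 16 were not called by edgeR, with 14 lower adjusted over the list alone (median -0.58, adjusted p = 1.08e-07); Col4a3, of the glomerular basement membrane, fell by 1.03 ± 0.17 and the fibrillar collagen gene Col5a2 by 2.86 ± 0.35. Of 22 cell cycle genes, 6 fell and 16 were not called, with 7 lower adjusted over the list alone (median -1.01, adjusted p = 2.24e-05); the replication helicase subunit Mcm6 fell by 1.02 ± 0.13 and Cdc6 by 1.45 ± 0.32, and without NC replicate 4 the median was -0.54. Of 12 T and NK cell markers, 2 fell and 10 were not called, with 6 lower adjusted over the list alone (median -0.93, adjusted p = 0.00607), and Cd4 fell by 1.65 ± 0.29. Of 3 tested B and plasma cell markers, 1 fell and 2 were not called, with 2 lower adjusted over the list alone (median -0.91, adjusted p = 0.00666); Jchain, which joins antibody units, fell by 5.45 ± 0.64 from 10.4 to 0.236 CPM. For the B cell list adjusted p = 0.501 with an estimated correlation, and for the other 3 lists adjusted p = 0.503 with an estimated correlation. Markers of other tissues varied too, in lists that were not called. Adipocyte markers summed to 17.4 to 20.5 CPM in NC and 5.15 to 15.6 in DN (list adjusted p = 0.124). Most of these counts were of Fabp4, with 1023 to 1238 in NC libraries and 334 to 869 in DN libraries. Adipoq had 1 to 21 in NC and 0 to 40 in DN, so the sums mainly show Fabp4 and not fat tissue. Haemoglobin genes summed to 25.8 to 95.8 CPM in NC and 5.89 to 263 in DN (0.198), with Hbb-bs, chosen after its values were seen, at 1063 to 3767 counts in NC, 229 to 437 in DN replicates 1 to 3 and 8515 in DN replicate 4.

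Lists of interferon-stimulated and protein-folding genes were called higher in DN, with most members not called. Of 20 interferon-stimulated genes, 7 rose and 13 were not called, with 15 higher adjusted over the list alone (median 1.75, adjusted p = 1.2e-07); Irf7, a transcription factor of the interferon response, rose by 2.55 ± 0.39 and Usp18 by 1.31 ± 0.29. Of 19 unfolded protein response genes, 7 rose and 12 were not called, with 12 higher adjusted over the list alone (median 0.70, adjusted p = 1.31e-06); the chaperone calreticulin (Calr) rose by 0.76 ± 0.16 and Hyou1, a chaperone of the endoplasmic reticulum, by 0.71 ± 0.19. Of 15 complement genes, 3 rose, 1 fell and 11 were not called, with 4 higher and 2 lower adjusted over the list alone (median 0.36, adjusted p = 0.0481). C4b rose by 4.17 ± 0.81, and its close copy C4a had 0 to 2 counts in NC libraries and 88 to 1381 in DN libraries; the 2 share sequence and are uncertain. For each of these 3 lists, adjusted p = 0.503 with an estimated correlation. Of 17 tubular injury markers, 3 rose and 14 were not called, with 6 higher adjusted over the list alone (median 0.58, adjusted p = 0.0127); Krt8 rose by 0.47 ± 0.10, and adjusted p = 0.527 with an estimated correlation. In DN replicate 4 alone Lcn2 reached 241 CPM and Havcr1 16.6. Without that library the injury list had a median of 0.28 (adjusted p = 0.337) and the complement list one of 0.10 (adjusted p = 0.250). The complement call was lost in 7 of 16 alternatives, among them RLE factors, the filter of at least 1 CPM in 4 libraries, and without NC replicate 4 or DN replicate 1.

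Lists of lipid and short-chain acyl genes were called lower, with most members not called. Of 20 cholesterol synthesis genes, 4 fell, 2 rose and 14 were not called, with 6 lower and 3 higher adjusted over the list alone (median -0.33, adjusted p = 0.0173); Cyp51, a sterol demethylase, fell by 1.74 ± 0.24 and Idi1, an isomerase of the isoprenoid units, by 1.26 ± 0.30, and adjusted p = 0.595 with an estimated correlation. Of 16 fatty acid synthesis genes, 4 fell and 12 were not called, with 5 lower and 1 higher adjusted over the list alone (median -0.22, adjusted p = 0.0267); Me1, the cytosolic malic enzyme, fell by 1.11 ± 0.13 and the desaturase gene Scd1 by 1.47 ± 0.20. Of 15 butyrate and short-chain acyl genes, 6 fell, 1 rose and 8 were not called, with 6 lower and 1 higher adjusted over the list alone (median -0.10, adjusted p = 0.0135). Bdh1, which interconverts ketone bodies, fell by 1.73 ± 0.19 and Acat1 by 0.82 ± 0.13. For both of the last lists adjusted p = 0.503 with an estimated correlation. Without DN replicate 4 the 3 lists were not called (adjusted p = 0.371, 0.171 and 0.186). The last 2 were not called without DN replicate 1 either. With 1 library left out, the median of the butyrate and short-chain acyl list ran from -0.25 to 0.0058, though camera kept its direction.

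Classical markers of diabetic kidney disease did not pass the test. The podocyte gene Nphs1 differed by -0.01 ± 0.14 (adjusted p = 0.988), and the glucose transporters Slc5a2 and Slc5a1 by 0.23 ± 0.22 and -0.00 ± 0.12 (adjusted p = 0.619 and 0.991). Havcr1 and Lcn2, markers of tubular injury, differed by 2.81 ± 1.33 and 3.74 ± 1.29 (adjusted p = 0.254 and 0.117), and the chemokine gene Ccl2 by 2.32 ± 1.28 (adjusted p = 0.325). These 3 values rest on DN replicate 4, without which they were -0.60, 0.54 and -1.74 (adjusted p = 0.674, 0.539 and 0.238). Ccl2 had 177 counts in that library, 1 to 4 in the other DN libraries and 5 to 14 in NC. Among matrix genes, Col1a1 differed by -1.38 ± 0.59, Col4a1 by -0.41 ± 0.15 and Fn1 by -0.83 ± 0.25 (adjusted p = 0.203, 0.120 and 0.0603); without DN replicate 4 Col1a1 differed by -2.54 (adjusted p = 2.09e-04). Fn1 passed without DN replicate 4 (-1.05, adjusted p = 0.0192) or NC replicate 3 (-0.96, adjusted p = 0.0436). The growth factor gene Tgfb1 differed by -0.14 ± 0.14 (adjusted p = 0.630). The gluconeogenic gene Pck1, the deacetylase gene Hdac2 and the monocarboxylate transporter gene Slc16a1 differed by 0.29 ± 0.20, 0.02 ± 0.16 and 0.17 ± 0.17 (adjusted p = 0.445, 0.960 and 0.622).

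In all, 669 genes were higher and 774 lower in DN than NC. There were 2340 genes with separated groups (13.3%, against 2.86% by chance). With library size only, in place of TMM, 503 were higher and 1103 lower, since the median of all genes was then -0.08, against 0.01 with TMM. Without NC replicate 1 or 3, 409 or 428 were higher. Of the 49 lists, 20 were called, 6 higher and 14 lower; with an estimated correlation 0 were called by camera, against 9 by fry. The endothelial, mesangial and macrophage lists, called lower at medians of -0.20, -0.28 and -0.33 (adjusted p = 0.0173, 0.0368 and 0.0175), each lost the call without DN replicate 1 (adjusted p = 0.0601, 0.197 and 0.0791) and without some other libraries.

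The second comparison asked which genes sodium butyrate changed within the disease model. Slc16a1, the monocarboxylate transporter that carries butyrate, lactate and ketone bodies across membranes, rose from 24.3 ± 3.88 CPM in DN to 55.4 ± 7.04 in DN+NaB (log2 fold change 1.19 ± 0.17, adjusted p = 0.0299, n = 4 per group). Rnf186, an epithelial ubiquitin ligase, rose from 37.1 ± 2.91 to 78.0 ± 12.3 CPM (1.07 ± 0.15, adjusted p = 0.0299). The lymphocyte genes Cxcr3, a chemokine receptor of activated T cells, and Cd5, a T cell surface protein, fell by 2.31 ± 0.30 (1.01 ± 0.264 to 0.202 ± 0.0387 CPM, adjusted p = 0.0299) and by 3.31 ± 0.49 (0.542 ± 0.151 to 0.0538 ± 0.0300 CPM, adjusted p = 0.0376). Each of the 4 genes had separated groups.

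**Figure D3:**
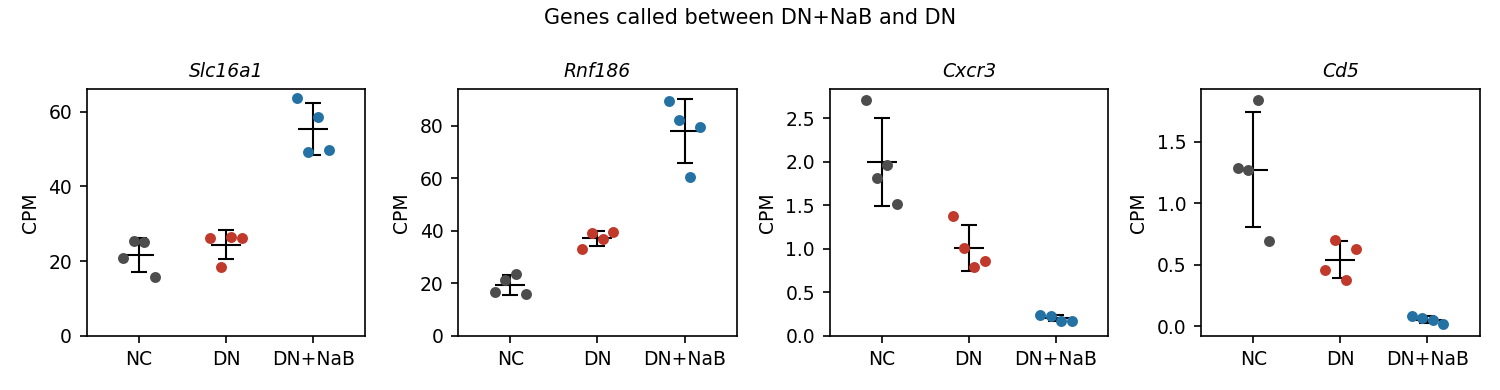
CPM of Slc16a1, Rnf186, Cxcr3 and Cd5, the 4 genes called between DN+NaB and DN, in the 12 libraries; points are libraries, the horizontal line is the group mean and the bars are ± 1 SD. Slc16a1 averages 55.4 CPM in DN+NaB against 24.3 in DN and 21.7 in NC, and Cxcr3 0.202 against 1.01 in DN.

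The T and NK cell markers were lower with sodium butyrate as a set. None of the 12 members passed the test over all genes by edgeR, and 11 were lower adjusted over the list alone (median -1.70, camera adjusted p = 1.01e-13; adjusted p = 0.0941 with an estimated correlation). Gzmb, a granule protease of cytotoxic cells, differed by -3.29 ± 0.62 (adjusted p = 0.0776), Cd8b1 by -3.72 ± 0.73 (0.0819) and Nkg7 by -1.54 ± 0.29 (0.0628). Among 18 macrophage and dendritic cell markers, 0 were called by edgeR and 2 were lower adjusted over the list alone (median -0.52, adjusted p = 3.68e-06; adjusted p = 0.585 with an estimated correlation); the antigen presentation genes H2-Ab1 and Cd74 differed by -2.98 ± 0.59 and -2.43 ± 0.52 (adjusted p = 0.0844 and 0.127). The median of that list was -0.19 without DN replicate 4, and its call was kept. Adipocyte and neutrophil markers also had lower medians (-0.66 and -1.75), in lists that camera did not call (adjusted p = 0.0896 and 0.0714). The 3 tested B and plasma cell markers had a median of 0.02 (adjusted p = 0.608).

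The circadian clock list was also called. None of 18 were called over all genes by edgeR, while 11 were lower and 2 higher adjusted over the list alone (median -0.59, adjusted p = 2.46e-04; adjusted p = 0.0721 with an estimated correlation). Per3, a repressor of the clock, differed by -1.49 ± 0.24 (adjusted p = 0.0507), Cry1 by -1.78 ± 0.36 (0.0842) and Tef by -0.71 ± 0.14 (0.0819). Per3 passed with DESeq2, limma-voom and 7 other settings.

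Other lists were called as well. Unfolded protein response genes were lower (median -0.35, 19 members, adjusted p = 8.68e-05) and intercalated cell markers higher (median 0.33, 12 members, 3 higher adjusted over the list alone, adjusted p = 2.22e-05), with 0 members of either called by edgeR; adjusted p = 0.585 with an estimated correlation for both. Without DN replicate 4 the unfolded protein response median was -0.23, and without DN+NaB replicate 2 it was -0.56. Foxi1, the transcription factor of intercalated cells, differed by 0.62 ± 0.15 and the chaperone gene Hspa5 by -0.59 ± 0.22 (adjusted p = 0.167 and 0.392). Nuclear genes of the respiratory chain were higher (median 0.20, 22 members, adjusted p = 8.68e-05), with 0 called by edgeR and 0 adjusted over the list alone, and adjusted p = 0.694 with an estimated correlation. The median was 0.09 without DN replicate 4. The inflammatory list was lower (median -0.76, 22 members, adjusted p = 2.74e-04), also with 0 called by edgeR and 0 adjusted over the list alone, and adjusted p = 0.694 with an estimated correlation. Without DN replicate 4, which had a score of 1.70 on that list against -0.23 to -0.13 in the other DN libraries, its median was -0.11 and it was not called (adjusted p = 0.196). Interferon-stimulated genes were lower (median -0.40, 20 members, 0 adjusted over the list alone, adjusted p = 0.00114; adjusted p = 0.739 with an estimated correlation), and lost the call without DN replicate 4 (adjusted p = 0.0750) or DN+NaB replicate 1 (adjusted p = 0.423).

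Of the genes named in advance, Havcr1 had 0.186 ± 0.173 CPM in DN+NaB and 4.46 ± 8.07 in DN, and Lcn2 5.48 ± 3.46 and 65.6 ± 117 (log2 fold changes -4.57 and -3.58, adjusted p = 0.348 and 0.410). The fold changes were -1.18 and -0.39 without DN replicate 4. Col1a1 differed by -0.90 ± 0.58 (0.651; 0.24 without DN replicate 4), Slc5a2 by 0.61 ± 0.22 (0.400) and Hdac2 by 0.00 ± 0.16 (0.995). Nphs1, Slc5a1, Col4a1, Fn1, Tgfb1, Ccl2 and Pck1 were not called either. Ccl2 went from -2.41 to 1.64 without DN replicate 4.

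**Figure D4:**
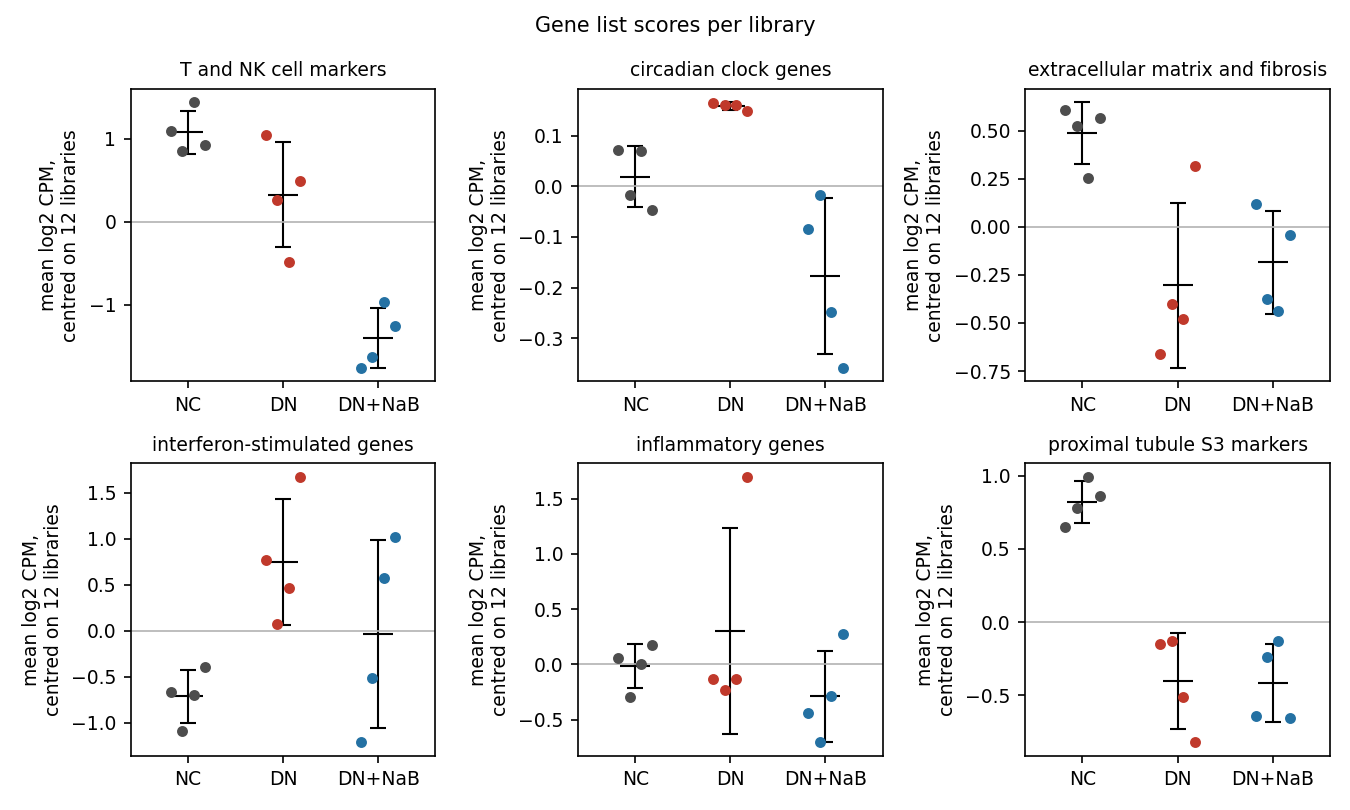
Mean log2 CPM of 6 gene lists in the 12 libraries, each gene centred on its mean over the 12 libraries; points are libraries, the horizontal line is the group mean and the bars are ± 1 SD. The T and NK cell score averages 1.08 in NC, 0.33 in DN and -1.40 in DN+NaB, and DN replicate 4 stands at 1.70 on the inflammatory list.

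In all, 2 genes were higher and 2 lower in DN+NaB than DN by edgeR, and 1726 had an unadjusted p under 0.05; DESeq2 called 83 and 186, and limma-voom 26 and 44. With library size only 8 were higher and 18 lower, and with RLE factors 8 and 14. The 4 calls were lost when only the 2 groups compared were fitted, and also without DN replicate 1, DN+NaB replicate 1 or DN+NaB replicate 4 (adjusted p of up to 0.151). Without DN replicate 2, 0 of the 2 higher and 1 of the 2 lower genes kept the call. These counts were 1 and 1 without DN+NaB replicate 2, and 1 and 0 without DN+NaB replicate 3. From 0 to 30 genes were higher and 0 to 37 lower when 1 library was left out, with the most without DN replicate 3. Groups were separated for 800 genes (4.56%, against 2.86% by chance). Of the 49 lists 16 were called, 8 in each direction, against 0 by camera with an estimated correlation and 2, the T and NK and the circadian lists, by fry.

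Whether sodium butyrate moved genes back towards NC was asked next. Rnf186 rose and Cxcr3 fell in both steps, from NC to DN and from DN to DN+NaB, and no gene was called in opposite directions by edgeR. Both calls between DN+NaB and DN were lost with only the 2 groups compared (adjusted p = 0.0820 for Rnf186) and without DN replicate 1, DN+NaB replicate 1 or DN+NaB replicate 4, and each gene was lost in further settings. DESeq2 called 41 genes in opposite directions and limma-voom 8. At an unadjusted p under 0.05 in both comparisons, 324 genes had opposite and 313 the same direction. Simulated unchanged groups gave 170 ± 14.6 and 0.95 ± 0.89 (SD), and independent lists 188 and 190. In the simulations DN did not differ from NC either, so their counts are no baseline for a real disease change that the treatment leaves alone. The covariance of the fold changes across genes was -0.0712, and -0.0650 in the simulations, with r = -0.18 and -0.50. With different DN libraries in each comparison it was 0.0632 ± 0.0484, above 0 in all 6 assignments; genes are not independent replicates. When different DN libraries served each comparison, 39.9% ± 9.63 of the genes called in DN moved in the opposite direction with sodium butyrate (mean ± SD of 6 assignments), against 42.7% of all genes. The assignments ran from 22.8% to 50.1% and were uneven: with DN replicates 2 and 3 set against NC and replicates 1 and 4 against DN+NaB, the share was 22.8% and the covariance 0.156, against 0.0240 to 0.0735 in the other 5. That assignment called 251 genes in the same direction in both comparisons and 14 in opposite directions, and the other 5 called 0 to 5 and 0.

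The third comparison set treated diseased cortex against NC. Bhmt rose by 4.84 ± 0.32, Hpd, of tyrosine breakdown, by 2.30 ± 0.18 (81.3 ± 4.80 to 402 ± 71.6 CPM, adjusted p = 2.29e-06), the phospholipase gene Pla2g5 by 2.57 ± 0.19, Rnf186 by 2.02 ± 0.15 and Slc16a1 by 1.35 ± 0.17 (adjusted p = 1.39e-04). Myo5a, a motor protein, fell from 70.2 ± 11.1 to 11.6 ± 1.75 CPM, Atp11a by 2.52 ± 0.15, Lpl, the lipoprotein lipase, by 1.85 ± 0.17 (358 ± 67.6 to 99.7 ± 18.9 CPM), Adhfe1 by 2.17 ± 0.14, Rnps1 by 2.06 ± 0.11 and Mpv17l by 1.88 ± 0.16. Sec14l3 had 0 to 4 counts per DN+NaB library. Slc5a2, the glucose transporter of the early proximal tubule, rose by 0.83 ± 0.22 (adjusted p = 0.0227) and Col1a1 fell by 2.28 ± 0.61 (adjusted p = 0.0287), but both lost the call without NC replicate 1, NC replicate 4, DN+NaB replicate 2 or DN+NaB replicate 3, with adjusted p of up to 0.0735 and 0.0811.

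Genes with shared sequence went in the same directions as in DN, and their values are as uncertain. Atp6v0c-ps2 rose by 5.64 ± 0.28 and Rpsa-ps10 by 3.07 ± 0.18, while Atp6v0c, Rpsa and Rpsa-ps2 fell by 2.72 ± 0.12, 2.33 ± 0.18 and 3.68 ± 0.30. Among other genes named by rule, Mrps23 rose by 5.59 ± 0.17, Cuedc1 by 4.38 ± 0.24 and Pianp by 5.07 ± 0.38.

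Immune cell lists were lower. Of 12 T and NK cell markers, 10 fell and 2 were not called, with 10 lower adjusted over the list alone (median -2.75, adjusted p = 1.45e-08); Lck, a T cell kinase, fell by 1.91 ± 0.28 and Cd3d, of the T cell receptor complex, by 4.18 ± 0.69. Adjusted p = 0.331 with an estimated correlation for this list and for the B and plasma cell list, of which 2 of 3 members fell and 3 were lower adjusted over the list alone (median -1.55, adjusted p = 0.00983). Of 18 macrophage and dendritic cell markers, 10 fell and 8 were not called, with 11 lower adjusted over the list alone (median -0.86, adjusted p = 2.08e-06; adjusted p = 0.553 with an estimated correlation); Csf1r, the receptor for a macrophage growth factor, fell by 0.89 ± 0.12 and Mrc1 by 1.57 ± 0.24. Of 22 cell cycle genes, 12 fell, 1 rose and 9 were not called, with 18 lower and 1 higher adjusted over the list alone (median -1.38, adjusted p = 8.38e-06; adjusted p = 0.596 with an estimated correlation); Mcm6 fell by 1.26 ± 0.13, while Tyms rose by 0.58 ± 0.13.

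Of 18 S1 and S2 markers, 7 rose and 11 were not called, with 9 higher adjusted over the list alone (median 0.54, adjusted p = 3.56e-05; adjusted p = 0.553 with an estimated correlation); Slc7a8, an amino acid transporter, rose by 1.13 ± 0.19 and Slc7a7 by 1.06 ± 0.15. Of 10 S3 markers, 5 fell, 1 rose and 4 were not called, with 6 lower and 1 higher adjusted over the list alone (median -0.66, adjusted p = 0.00157; adjusted p = 0.553 with an estimated correlation); Slc7a13 fell by 2.93 ± 0.28 and Slc5a8, a sodium-coupled carrier of butyrate, by 1.48 ± 0.18. Of 26 matrix genes, 9 fell and 17 were not called, with 11 lower adjusted over the list alone (median -0.41, adjusted p = 3.91e-04; adjusted p = 0.780 with an estimated correlation), and Col5a2 fell by 3.10 ± 0.36. Of 11 male-biased genes, 7 fell, 1 rose and 3 were not called, with 8 lower and 1 higher adjusted over the list alone (median -1.14, adjusted p = 0.00983; adjusted p = 0.780 with an estimated correlation), and Kap fell by 2.75 ± 0.38. Of 7 female-biased genes, 3 rose and 4 were not called, with 4 higher adjusted over the list alone (median 0.56, adjusted p = 0.0164; adjusted p = 0.544 with an estimated correlation), and Abcc3 rose by 2.34 ± 0.23; the call ended without DN+NaB replicate 3 (adjusted p = 0.0527). Of 20 interferon-stimulated genes, 5 rose and 15 were not called, with 6 higher adjusted over the list alone (median 1.04, adjusted p = 0.0164; adjusted p = 0.8286 with an estimated correlation), and Usp18 rose by 1.72 ± 0.29; the call ended without NC replicate 2, DN+NaB replicate 3 or DN+NaB replicate 4 (adjusted p = 0.0700, 0.0705 and 0.128). Of 4 adipocyte markers 1, the fatty acid carrier gene Fabp4, fell by 1.44 ± 0.30 and 3 were not called, with 2 lower adjusted over the list alone (median -1.54, adjusted p = 0.0395; adjusted p = 0.544 with an estimated correlation); the call was lost in 9 of 15 alternatives, among them without DN+NaB replicate 4 (median -1.33, adjusted p = 0.0694).

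In all, 1161 genes were higher and 1568 lower in DN+NaB than NC, and 4884 had separated groups (27.9%, against 2.86% by chance). With library size only the numbers were 875 and 2070, as the median of all genes was then -0.12, against -0.01 with TMM. Without DN+NaB replicate 2, 1043 were lower. Of the 1443 genes called between DN and NC, 1151 (79.8%) were called in the same direction between DN+NaB and NC: 525 higher and 626 lower, against 44.3 and 69.2 for independent lists, and 0 in simulated unchanged groups. With separate NC libraries for each comparison, 207 and 286 genes were shared (means of 6 assignments), against 8.33 and 20.5 for independent lists. The covariance of the fold changes was 0.591, against 0.0640 in the simulations and 0.647 with separate NC libraries. In the simulations neither diseased group differed from NC, so their values are no baseline for groups that both differ from NC.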

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

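Among the tests in this part, those of gene neighbours, of lymphoid tissue and of the hour of the day were chosen after the results were seen, while the splits of the libraries and the tests without single libraries were set before. Some limits were also changed after a first value was seen. For shared reads and for overlapping neighbours the distance tested was changed because the ratio at 11 to 50 genes (1.06 over all genes) had fallen between the limits first written. For the genetic background the comparison with the highest permutation was first read as an exclusion, and the limit was then loosened. For lymphoid tissue a minimum of 5 B cell markers was added after the first limit had been met. These 4 tests therefore weigh less than tests fixed in advance.

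Genes called between DN and NC lay next to each other in the gene order more often than chance would place them: 202 neighbouring pairs were seen and 113 expected, a ratio of 1.79 (permutation p = 1e-04, the smallest that 10000 permutations can give). The ratio stayed at 1.54 among protein-coding genes with no tested pseudogene copy named after them. That argues against reads shared with such named copies as the whole cause. Genes whose copies carry other names, and families of protein-coding genes such as Gsta1 and Gsta2, stayed in that set. Reads shared among those were therefore not tested. Over all tested genes 2 to 10 apart the ratio was 1.28, which argues against reads counted for overlapping neighbours as the whole cause. Whether such reads add to the higher ratio of next neighbours stays open, and gene families stayed in this set too. A genetic background that differs between control and diseased mice may be a source, but it cannot be told apart from regional regulation here: at 11 to 50 genes the ratio of 1.06 (p = 6e-04) did not pass the highest permutation (1.06), and for as many top genes of DN+NaB against DN it was 1.03 over all genes, but 1.05 in both comparisons among protein-coding genes without copies. On the other side, the ratio for next neighbours was 1.79 against 1.28 for those top genes. Of 318 windows of 50 genes, 5 held 12 or more calls, against 0.202 expected. The calls in 1 of these windows are mostly immunoglobulin kappa genes, and another holds the Gsta gene family. Genes named in the Results lie there too: Greb1 and Odc1 in a window with 16 calls, Rnf186 and Pla2g5 in 1 with 12, and Myo5a in the Gsta window. Whether their values rest on the region was not tested. The labels give the same strain for all mice.

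T and NK cell markers were lower as a set in DN+NaB than in DN by camera with its preset correlation, with 0 of 12 members called by edgeR and adjusted p = 0.0941 with an estimated correlation. No single library accounted for the call: the median nearest 0 with 1 library left out was -1.41, against -1.70. Among the 35 splits of the 8 libraries, no other gave this list a smaller p. The same held for the clock list. Many lists were ranked in this way, and chance alone can place some of them first, so the rank adds little. Over the lists called in this comparison, the splits with a p as small, the real one included, numbered from 1 to 23. The highest number was that of the injury list, with 16 for the interferon-stimulated and 13 for the inflammatory list. Lymphoid tissue taken along with some DN kidneys could be a source and cannot be told apart from fewer T cells in the kidney, since the median of the B cell markers was 0.0214 but only 3 were tested, near the floor, and of these Cd79b differed by -0.87. An effect of the treatment itself stays open and untested.

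The clock list was called between DN+NaB and DN by camera with its preset correlation, with 0 of 18 members called by edgeR and adjusted p = 0.0721 with an estimated correlation. The median nearest 0 with 1 library left out was -0.42, against -0.59, with the list called each time at the preset correlation. Genes that peak at the other end of the day (Arntl, Npas2, Nfil3, Clock and Cry1) had a median of 0.87, and the Per and Dbp group one of -0.87, with Cry1 (-1.78) and Clock (-0.08) against the first and Nr1d1 (0.58) and Bhlhe41 (0.01) against the second. An hour of dissection that differed between the groups may be a source, and it cannot be told apart from a phase set by sodium butyrate, since the labels give no hour.

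Among the 35 splits of 4 against 4 libraries, only the real one gave 1443 genes called between DN and NC, and the highest other gave 2. For DN+NaB against NC only the real one gave 2729, and the highest other gave 1. Such ranks make a chance division of the libraries unlikely but cannot exclude it, since 1 of 35 is the smallest share possible. Every other split also mixes libraries of both groups, so a real difference widens its spread and lowers its count. For DN+NaB against DN, 3 splits gave 4 or more genes, so chance cannot be excluded; the highest other gave 152, many times the real count, which points to a structure of the samples other than the groups. For the gene lists chance stays open in every comparison. The 20 lists of DN against NC, or more, came from 3 splits (highest other 24). The 16 of DN+NaB against DN, or more, came from 11 (20), and the 11 of DN+NaB against NC, or more, from 19 (17).

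Single libraries stood far from the other 3 of their group in 21 of 219 groups of values checked, and chance would give 10.95. DN replicate 4 accounted for 10. Gpx3 took 6.05% of its counts (6.79 to 6.87 in the other DN libraries). Its intercalated cell score was -0.56 (-0.20 to -0.14) and its inflammatory score 1.70 (-0.23 to -0.13). In CPM it had Lcn2 at 241 (2.46 to 11.1), Col1a1 at 114 (12.6 to 23.8), Havcr1 at 16.6 (0.106 to 0.768), Ccl2 at 2.86 (0.0151 to 0.0704), Lpl at 125 (95.8 to 96.8), Adhfe1 at 56.8 (75.4 to 78.7) and Ube2d-ps at 17.7 (21.8 to 22.4).

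The other libraries that stood apart did so for fewer values. DN replicate 3 had 0.361% of counts on mitochondrially encoded protein genes (2.598 to 2.90), Ctdnep1 at 9.48 CPM (5.70 to 6.02) and Rpsa-ps2 at 0.2725 (0.158 to 0.178). DN replicate 2 had Slc16a1 at 18.5 CPM (26.2 to 26.4), and DN replicate 1 an NRF2 score of -0.0281 (-0.00 to 0.00). DN+NaB replicate 3 had Havcr1 at 0.444 CPM (0.0851 to 0.115). NC replicate 4 had scores of 0.0311 for cholesterol synthesis (0.29 to 0.31), -0.02255 for fatty acid synthesis (0.22 in the others) and -0.14 for ribosomal protein genes (0.28 to 0.34), and Rpsa at 465 CPM (615 to 637).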

How the results depend on the processing

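Among the alternatives, only the fit to protein-coding genes was chosen after the data were seen. No count, no camera direction of a called list and no called named gene reversed. The median of the butyrate and short-chain acyl list in DN against NC reached 0.0058 with 1 library left out. Some genes not called changed sign: Ccl2 was -1.74 in DN against NC and 1.64 in DN+NaB against DN without DN replicate 4. Without that library Havcr1 was -0.60 in DN against NC and Col1a1 0.24 in DN+NaB against DN. Between DN and NC, 669 genes were higher and 774 lower: DESeq2 gave 1032 higher, limma-voom 1042 and 1220, and a log2 fold change of at least 1 gave 325 and 418. The other settings gave 461 to 694 and 593 to 1153. Without 1 library the counts were 409 (without NC replicate 1) to 921 (without DN replicate 4) and 533 to 1055. Between DN+NaB and DN, 2 were higher and 2 lower: RLE factors gave 8 and 14, library size only 8 and 18, no low-count filter 9 and 18, at least 1 CPM in 4 libraries 7 and 10, protein-coding genes alone 8 and 15, DESeq2 83 and 186, limma-voom 26 and 44. With only the 2 groups compared, edgeR gave 0 and 0, against 1726 at an unadjusted p under 0.05 in all 12 libraries. Without 1 library the counts ran from 0 (DN replicate 1) to 30 and 37 (DN replicate 3). Between DN+NaB and NC, 1161 were higher and 1568 lower: limma-voom gave 2201 and 2730, only the 2 groups 1783 higher, a log2 fold change of at least 1 444 and 831. The other settings gave 875 to 1478 and 1372 to 2183, and leaving out 1 library 790 to 957 and 1043 (without DN+NaB replicate 2) to 1398 (without DN+NaB replicate 1). Gene lists called numbered 20, 16 and 11 in the 3 comparisons: 0, 0 and 0 by camera with an estimated correlation, 9, 2 and 14 by fry, and 14 to 21, 14 to 20 and 9 to 14 without 1 library. Genes that sodium butyrate moved back numbered 0 by edgeR: RLE factors gave 2, library size only 1, no low-count filter 1, at least 1 CPM in 4 libraries 1, protein-coding genes alone 2, DESeq2 41, limma-voom 8, and leaving out 1 library 0 to 3. The share moved in the opposite direction was 37.3% to 40.9% under the other settings and 36.01% to 43.6% without 1 NC or DN+NaB library; DN libraries could not be left out of it. Of the named genes called, 34 of 82 between DN and NC lost the call in 1 or more settings, 4 of 4 between DN+NaB and DN, and 10 of 63 between DN+NaB and NC. With the replicate number as a block, 653 and 763, 4 and 3, and 1260 and 1631 genes were called, 21, 18 and 12 lists, and 0 genes moved back; between DN+NaB and DN the block kept 1 of the 2 higher and 1 of the 2 lower genes, and Rnf186 and Cd5 lost the call (adjusted p = 0.0536 and 0.0576). Libraries with the same number correlated at -0.09 to 0.20, -0.25 to 0.27 and -0.07 to 0.22 in the 3 comparisons. Those with different numbers correlated at -0.27 to 0.22, -0.29 to 0.32 and -0.24 to 0.20, so the values do not show that the numbers pair the samples. Pairs of replicates 4 were positive throughout (0.20, 0.27 and 0.22), as were pairs of replicates 2 (0.05, 0.12 and 0.11), while those of replicates 1 and 3 took both signs. A feature shared by the replicates 4 is not excluded. Except where a value was given above, the cause of a change was not tested. At these depths a count of 0 in a library allows up to 3.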

Other observations

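The lists and the genes named here follow the rule set in advance, but Rpl3 and Kl were picked out for their values in single libraries after these were seen. Several lists not described above differed between DN+NaB and DN by camera, with 0 members called by edgeR in each. Markers of the distal and connecting tubule were higher (median 0.24, 11 members, 3 higher adjusted over the list alone, adjusted p = 0.00649), as were S1 and S2 markers (median 0.17, 18 members, 1 higher adjusted over the list alone, adjusted p = 0.00146), NRF2 targets (median 0.18, 21 members, 2 higher adjusted over the list alone, adjusted p = 0.00401) and ribosomal protein genes (median 0.14, 25 members, 0 adjusted over the list alone, adjusted p = 0.00611). NADPH oxidase genes were lower (median -0.87, 7 members, 4 lower adjusted over the list alone, adjusted p = 0.0121). With an estimated correlation the adjusted p was 0.585 for the distal, NRF2 and NADPH oxidase lists, 0.694 for S1 and S2, and 0.739 for ribosomal protein genes. Without DN replicate 4 the S1 and S2 median was 0.05 and the NADPH oxidase median -0.29 (adjusted p = 0.0552 for both), and without DN replicate 1 the ribosomal median was 0.08 (adjusted p = 0.104).

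The injury list was lower (median -0.59, adjusted p = 0.0425; 0.746 with an estimated correlation) and the matrix list higher (median 0.16, adjusted p = 0.0425; 0.811 with an estimated correlation) in DN+NaB than DN, with 0 of 17 and 0 of 26 members called by edgeR and 1 higher and 0 adjusted over the list alone. The injury call was lost in 7 of 16 alternatives and the matrix call in 8 of 16, with library size only among them for both. Both also depended on single libraries. Without DN replicate 4 the injury median was -0.07 (adjusted p = 0.831), and without DN replicate 1 the matrix median was 0.14 (adjusted p = 0.662). The mesangial list was higher (median 0.24, adjusted p = 0.0352; 0.729 with an estimated correlation; 0 of 12 called by edgeR and 0 adjusted over the list alone), but not without DN replicate 1 or DN+NaB replicate 1 (adjusted p = 0.256 and 0.316).

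Other genes in DN against NC belonged to lists that were not called. Igf1 fell by 1.54 ± 0.29 and Igfbp5 rose by 0.75 ± 0.14 in the insulin list (adjusted p = 0.153 for the list). Ace, which makes angiotensin II, fell by 1.64 ± 0.20 in the renin-angiotensin list (0.248). Pvalb, of the distal convoluted tubule, rose by 2.67 ± 0.26 (0.912), and of 16 podocyte markers 2 rose, among them Clic5 (0.65 ± 0.13), and 2 fell, among them Tcf21 (-0.72 ± 0.21), with 2 higher and 4 lower adjusted over the list alone (0.858). The histone deacetylase and acetyltransferase list was not called between DN+NaB and DN (adjusted p = 0.542), nor was the butyrate transport list that holds Slc16a1 (0.910).

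Rpl3, a ribosomal protein gene, had 6642 to 7856 counts in NC libraries and 128 to 215 in DN libraries, and 184 to 219 in DN+NaB replicates 2 to 4, but 3237 in DN+NaB replicate 1. In CPM that library had 55.1, against 92.1 to 120 in NC. Its copies Rpl3-ps1 and Rpl3-ps2 rose by 0.78 and 2.51 between NC and DN, so its value is uncertain. At other genes DN+NaB replicate 1 was far from NC: Mrps23 had 34.9 CPM (0.541 to 0.934 in NC libraries) and Atp6v0c 9.19 (48.97 to 62.2). An exchange or an equal mixture with an NC library would not give these values. Whether this mouse differed in genetic background, or was another mouse than its label says, was not tested and stays open, since the counts hold no genotypes. Kl, the klotho gene, had 7.84, 55.5, 8.33 and 34.1 CPM in DN+NaB replicates 1 to 4, and 3.21 to 7.39 in NC and DN libraries. Kl is a member of the distal and connecting tubule list, and that list was not tested without it.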
